A study of Canis lupus familiaris with 12 samples.

How the data were processed

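DNA of 12 canine mammary carcinomas was measured by array comparative genomic hybridisation, in which tumour DNA and normal mammary DNA carry different dyes and compete for the same probes. The labels name 8 simple carcinomas, of which simple carcinoma 8 is inflammatory, and 4 complex carcinomas. Per the labels, each tumour came from a different dog, and the reference was normal mammary DNA of the same dog, except for complex carcinoma 3, whose reference is labelled as tissue of the dog that gave simple carcinoma 1.

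The deposited values are log2 ratios per probe, which the authors made by a spatial correction and a normalisation of the 2 channels. In the 10 files that hold channel values, the deposited corrected log2 ratio equals the normalised log2 brightness of the test channel minus that of the reference channel. The files of complex carcinomas 3 and 4 hold the corrected ratio without channel values. The normalisation method, its software and the genome build are not given in the sources used here, and coordinates are those of the files. Per the file headers, the test channel was read at 532 nm and the reference at 635 nm. The labelling protocol puts test DNA in Cy3 and reference DNA in Cy5, whereas the dye field of the labels names the opposite dyes for tumour and normal. The ratio was read as tumour over normal from the headers and the protocol, and every sign would turn if the dye field held instead.

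Each array had 389319 probes with a median spacing of 4550 bp, of which 370640 lay on the 38 autosomes, 17661 on X and 1018 on unplaced or mitochondrial sequence. The number of arrays, 8 and 4, limits the precision. Ratios were centred on the autosomal median of each array and reduced to medians of 21940 bins of 100 kb with at least 3 probes and of 2220 bins of 1 Mb. Each autosome was segmented by exact least-squares optimal partitioning with a penalty of 3 times the noise variance times the logarithm of the number of bins and at least 5 bins per segment. A segment was called altered from a median of 0.2 in the higher direction or -0.2 in the lower direction. A step was a boundary between neighbouring segments whose medians differed by at least 0.2. The spread of an array was the SD of its 1 Mb bin medians. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

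The altered share of the autosomes, the number of steps and the spread were compared between the subtypes by a two-sided exact permutation test over all 495 regroupings of the arrays, with Benjamini-Hochberg adjustment over these 3 measures. The 1 Mb bins and the means of the 38 autosomes were tested with limma, each subtype against 0 and simple against complex in a single fit, with an adjusted p under 0.05 as the threshold. Bins altered in more simple carcinomas than their altered shares give by chance were sought with 1000 circular shifts of each array's calls, with the 95th percentile of the genome-wide maximum as the limit. No paired comparison of the subtypes was possible, since they share no dogs.

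The groups, the tests above, the thresholds, 9 gene lists and the rule for naming results were fixed before the data were examined. The Fisher's exact test of the lists was not part of that plan, and the chromosomes it uses were chosen from these data. The rule named the 6 autosomes altered over at least 50% of their length in the most simple carcinomas, the 6 with the lowest p between subtypes, recurrent regions past the chance limit, and the 10 segments of at most 5 Mb with the largest absolute medians. It also named the autosomes that carry a set of cancer genes, among them MYC, ERBB2, BRCA1, BRCA2, CDKN2A, RB1, CCND1, PIK3CA and ESR1. No gene annotation of the build of the arrays was used, so no gene-level values were computed, and the carrying autosome was read from a gene table of assembly UU_Cfam_GSD_1.0.

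The alternatives varied the threshold, penalty, bin size, centring, hybridisation set, reference dog, subtype, chromosomes, probe minimum, limma options and each array in turn. Alternatives on simple carcinomas 4 and 8 as a pair, on the files with channel values, on the ratio after the spatial correction alone, on the set as a random block, on each subtype fitted alone, on recurrence with simple carcinomas 4 and 8 counted once and on probe brightness were added after the data were seen. X was left out of the main tests because it depends on sex and on the reference dog. Unplaced and mitochondrial probes were left out because they have no place on an autosome.

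The segmentation was tested on simulated data with changes added to normal noise of each array's size, without correlation between neighbouring bins. It recovered 98.3% to 100% of changed bins at -0.3 and 0% to 0.833% at -0.15, over sizes from 0.5 Mb to a whole chromosome. Recovery was counted at the call threshold of -0.2. A change of -0.15 fell short of it in advance, so that value is no limit of the segmentation itself. The limma test, run on simulated data with 200 of 2220 bins changed between groups of these sizes, recovered 0% at -0.1, 44.5% at -0.2 and 89.5% at -0.4. The simulated bins were independent, and each had the same spread in both groups, taken from all arrays together. Real bins move together along chromosomes, and the spread between simple carcinomas was larger. These percentages are therefore not the power of the real comparison.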

Results

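Relative DNA copy number was measured in 8 simple and 4 complex canine mammary carcinomas on 2-colour tiling arrays, as log2 ratios of tumour over normal mammary DNA. Simple carcinomas grow from a single epithelial cell kind, whereas complex carcinomas hold proliferating epithelial and myoepithelial cells. Each array had 389319 probes, and the number of arrays limits the precision. By the file names there were 3 hybridisation sets, of which 1 held simple carcinomas 1 to 3, 1 held complex carcinomas 3 and 4, and the largest held simple carcinomas 4 to 8 and complex carcinomas 1 and 2. Only that set, of 7 arrays, held both subtypes. By the same names, its arrays and no others were a second hybridisation. Simple carcinoma 8 is labelled inflammatory. Signs below take the ratio as tumour over normal from the file headers and the labelling protocol. The dye field of the labels gives the opposite, and if it held, every gain named here would be a loss.

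The first question, which the series states as its purpose, was whether copy number differs between simple and complex carcinomas, and it was asked first for the genome as a whole. Among simple carcinomas, 4 tumours carried changes over whole chromosomes past the threshold of 0.2, mostly in the lower direction. Simple carcinomas 1, 4, 5 and 7 had 44.2%, 38.8%, 41.4% and 37.6% of their autosomal bins altered. Simple carcinomas 3 and 6 had 0.438% and 1.34%, in a few focal regions, and simple carcinomas 2 and 8 had 0%. No complex carcinoma exceeded 0.264% at this threshold, the value of complex carcinoma 3, and complex carcinomas 2 and 4 had 0%. At a threshold of 0.1, simple carcinoma 8 had 34.8% of its bins altered, in whole-chromosome changes of smaller size. Simple carcinomas 2, 3 and 6 then had 0%, 14.1% and 10.6%, and complex carcinomas 1 and 3 had 13.3% and 2.66%. The means of simple carcinoma 3 on chromosomes 13, 38, 14 and 34 were 0.19, 0.15, 0.15 and 0.14. Steps of at least 0.1 numbered 114 in complex carcinoma 1 and 103 in simple carcinoma 6, against 5 in simple carcinoma 8. Complex carcinoma 1 and simple carcinoma 6 shared a long-range wave, described below. Whether that wave gave these steps was not tested. No autosome mean of a complex carcinoma lay beyond 0.1 in either direction. Autosomes altered over at least 50% of their length numbered 17, 15, 16 and 14 in simple carcinomas 1, 4, 5 and 7 and 0 in each of the other 8 arrays.

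The altered share averaged 20.5% ± 21.5 (SD, n = 8) in simple and 0.113% ± 0.134 (SD, n = 4) in complex carcinomas, a difference of 20.4 points that did not pass a two-sided exact permutation test (p = 0.0768, adjusted over 3 measures 0.115). Without simple carcinoma 2, or without simple carcinoma 8, the exact permutation p was 0.0364 (adjusted 0.0545). The spread of 1 Mb log2 ratios was 0.146 ± 0.0686 (SD, n = 8) in simple and 0.0422 ± 0.0194 (SD, n = 4) in complex carcinomas, a difference of 0.103 that passed the exact permutation test (p = 0.0121, adjusted 0.0364). When each array in turn was left out, the adjusted exact p was 0.0182 without simple carcinoma 2 and between 0.0545 and 0.109 without each of the others, where the adjusted call was lost. Within the hybridisation set that held both subtypes, the difference in spread was 0.105 with an exact permutation p of 0.0952, the smallest that 5 against 2 arrays allow. Copy number steps averaged 9.25 ± 9.56 (SD, n = 8) and 4.25 ± 5.68 (SD, n = 4), with an exact permutation p of 0.4 (adjusted 0.4). The profiles of simple carcinomas 4 and 8 correlated at 0.97 over 1 Mb bins, so these 2 are not independent replicates. With the pair counted as 1 sample, the adjusted exact permutation p for the spread was 0.0545, and the adjusted call was lost. Complex carcinoma 3 had another dog's reference.

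**Figure D1:**
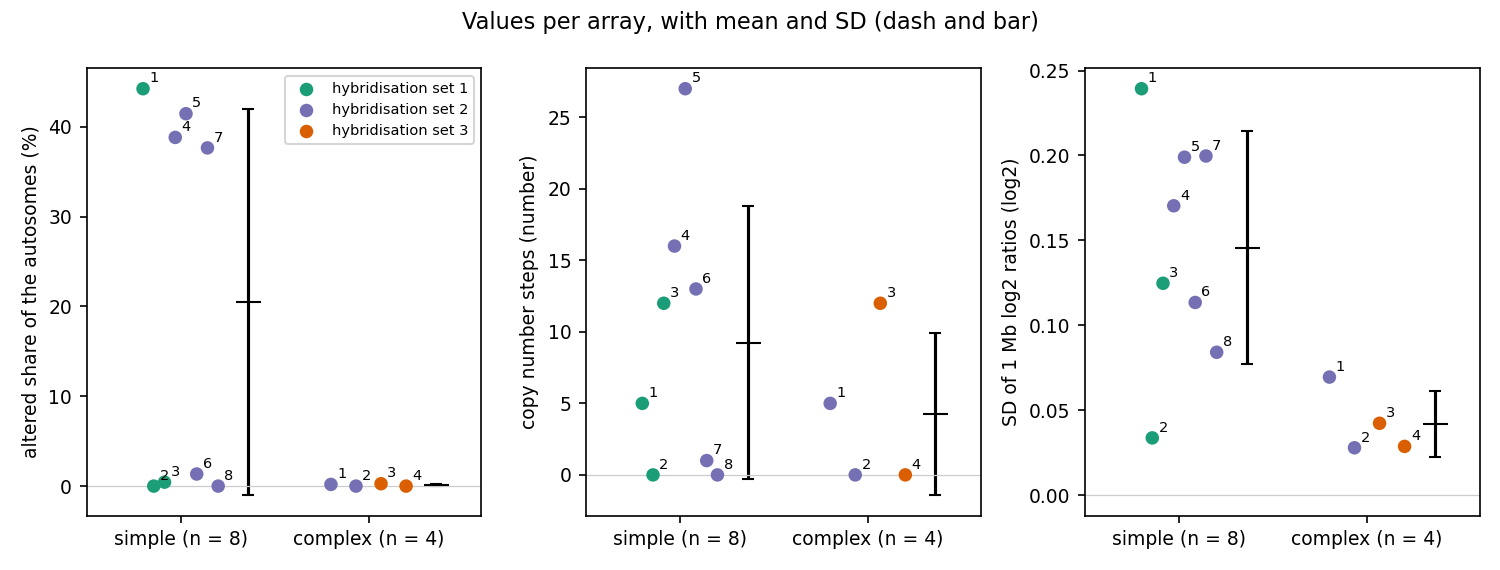
Altered share of the autosomes (percent), copy number steps (number) and spread of 1 Mb bins (SD of log2 ratios) for each array (points), with the mean and SD of 8 simple and 4 complex carcinomas. Altered shares of simple carcinomas 1, 4, 5 and 7 lie between 37.6% and 44.2%, and no complex carcinoma exceeds 0.264%.

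**Figure D2:**
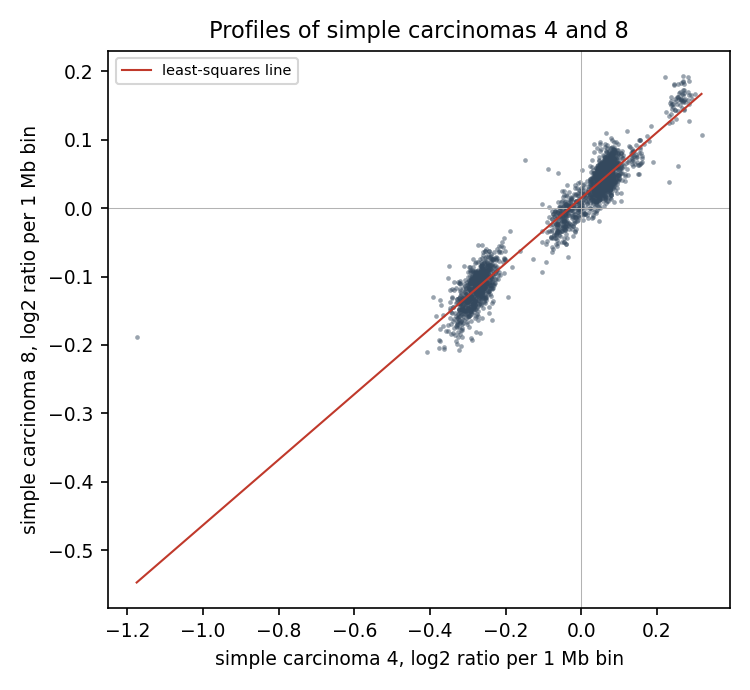
Log2 ratio of each 1 Mb bin (points) in simple carcinoma 4 (horizontal axis) and simple carcinoma 8 (vertical axis), with the least-squares line. The slope of simple carcinoma 8 on simple carcinoma 4 is 0.478, and the correlation over the bins is 0.97.

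The next question was which chromosomes were changed in the same direction in simple carcinomas. Losses were shared on chromosomes 3, 5, 15, 16, 18, 21 and 36, each lower over at least 50% of its length in simple carcinomas 1, 4, 5 and 7. Simple carcinoma 8 was lower on the same 7 chromosomes with means from -0.14 to -0.11, so that 5 of 8 simple carcinomas had a mean below -0.1 on each. Its profile correlated with that of simple carcinoma 4 at 0.97, so that count does not rest on independent tumours alone. Chromosomes 2, 27 and 30 were lower in 3 simple carcinomas. Gains were fewer, and chromosome 13 was the only autosome higher over at least 50% of its length in as many as 3 simple carcinomas. In all, 27 autosomes were altered over at least 50% of their length in at least 1 simple carcinoma, of which 23 were only lower, 3 only higher and 1, chromosome 35, went both ways.

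Among the autosomes named by the rule, chromosome 5 had a mean log2 ratio of -0.18 ± 0.14 (SD, n = 8) in simple carcinomas, below 0 in 8 of 8, and -0.02 ± 0.03 (SD, n = 4) in complex carcinomas. Chromosome 21 averaged -0.17 ± 0.15 (SD, n = 8) in simple carcinomas, below 0 in 8 of 8, with -0.0017 and -0.0010 in simple carcinomas 2 and 6. Chromosomes 15 and 16 averaged -0.17 ± 0.15 and -0.17 ± 0.16 (SD, n = 8), each below 0 in 7 of 8. Chromosome 3 averaged -0.17 ± 0.15 (SD, n = 8), below 0 in 6 of 8, and chromosome 18 averaged -0.16 ± 0.16 (SD, n = 8), below 0 in 7 of 8. Chromosome 13 averaged 0.22 ± 0.25 (SD, n = 8), above 0 in 8 of 8 and over 0.1 in 5 of 8. It was at 0.79 in simple carcinoma 1, 0.28 in simple carcinoma 5 and 0.26 in simple carcinoma 4. Simple carcinomas 3 and 8 were at 0.19 and 0.16. Simple carcinomas 2, 6 and 7 were near 0, at 0.011, 0.010 and 0.042. The mode of simple carcinomas 6 and 7 lay 0.0295 and 0.0455 above the median, so both fall below 0 with centring on the mode. Chromosome 36, chosen after its values were seen, averaged -0.16 in simple carcinomas and was below 0 in 5 of 8.

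Against 0, limma called 16 of 38 autosomes in simple carcinomas, 9 lower and 7 higher. Chromosomes 3, 5, 15, 16 and 21 each had an adjusted p of 0.012, chromosome 18 had 0.0148 and chromosome 13 had 0.0262. With arrays centred on the mode in place of the median, 12 autosomes were called, 11 lower and 1, chromosome 13, higher. Thus chromosomes 4, 14, 17, 24, 31 and 34, called higher at means of 0.04 to 0.09, lost that call with the centring. The fit shares its spread with the complex carcinomas. In simple carcinomas fitted alone, limma called 5 autosomes, chromosomes 3, 5, 15, 16 and 21, each lower with an adjusted p of 0.0495. Without simple carcinoma 1, 4 or 7, the joint fit called 10, 9 and 10 autosomes, and chromosome 13 had adjusted p values of 0.0525 without simple carcinoma 4 and 0.0505 without simple carcinoma 5. With simple carcinomas 4 and 8 counted as 1 sample, it called 12 autosomes, 10 lower and 2 higher. Without both simple carcinomas 4 and 8, it called 0, with 17 at an unadjusted p under 0.05 against 20 with all arrays and a lowest adjusted p of 0.0539. The mean of chromosome 5 was then -0.17 and that of chromosome 15 was -0.16, close to their values with all arrays.

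Of 2220 bins of 1 Mb, limma called 820 in simple carcinomas against 0, 569 lower and 251 higher, and 677 with arrays centred on the mode, 641 lower and 36 higher. With probe brightness taken out of each array, which also centres it on the mean, 1117 bins were called, 536 lower and 581 higher, so the excess of lower bins depended on that setting. With simple carcinomas 4 and 8 counted as 1 sample, 573 bins were called, 470 lower and 103 higher. In simple carcinomas fitted alone it called 0 bins, with 849 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0505. Without simple carcinoma 1, 4 or 7, the joint fit called 536, 424 and 487 bins, and without both simple carcinomas 4 and 8 it called 0, with 840 at an unadjusted p under 0.05 against 1044 with all arrays.

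**Figure D3:**
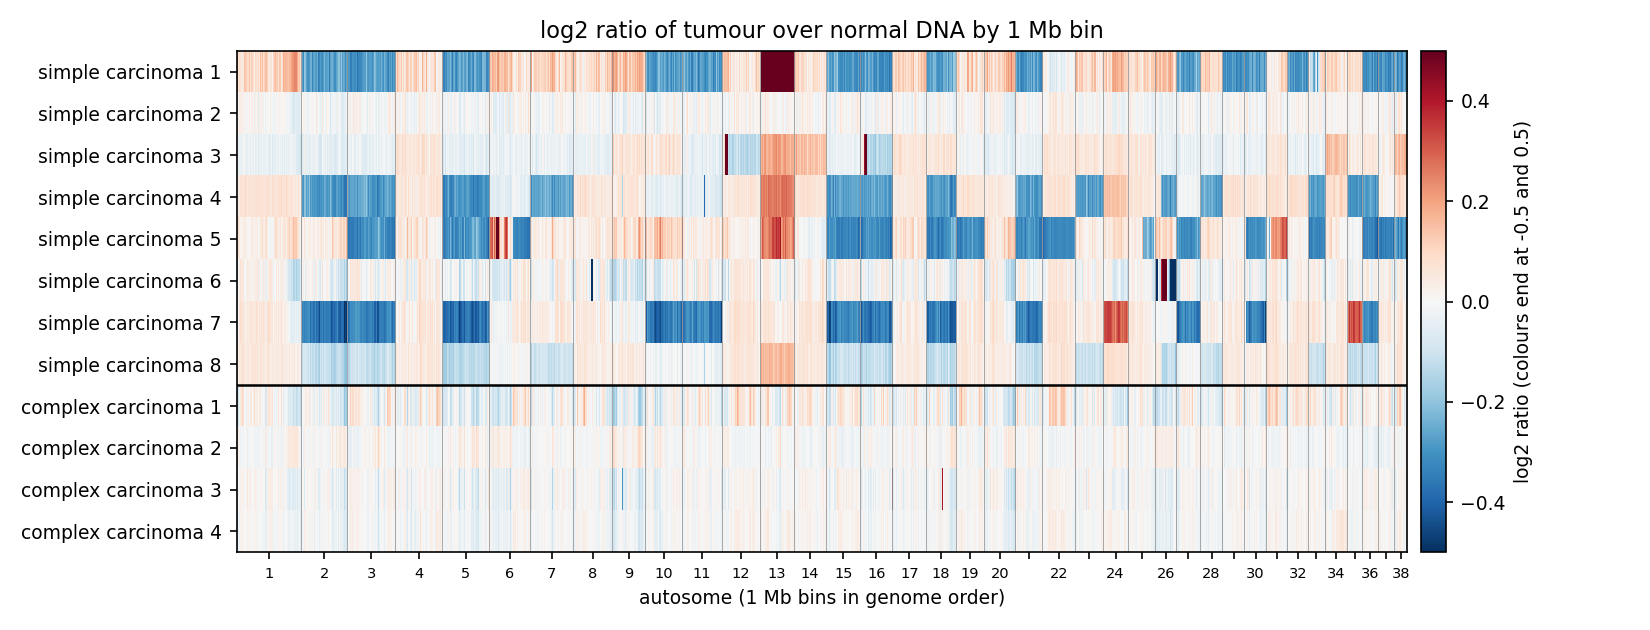
Log2 ratios of 1 Mb bins along the 38 autosomes (horizontal axis) for 8 simple and 4 complex carcinomas (vertical axis), centred on each array's autosomal median. Chromosomes 3, 5, 15, 16, 18, 21 and 36 are lower over at least 50% of their length in 4 of 8 simple carcinomas and in 0 of 4 complex carcinomas.

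A further question was whether these losses and gains coincide in more tumours than their extent gives by chance. The most shared gain covered chromosome 13 from 3000001 to 67000000, higher in 3 of 8 simple carcinomas over 64 bins. The most shared losses, over 436 bins, were lower in 4 of 8. Neither exceeded its limit in the circular-shift test, which was 3 arrays for gains and 5 for losses, so 0 bins were called recurrent. Only simple carcinomas 1, 4, 5, 6 and 7 had any lower call, so no bin could exceed 5 for losses. For losses the outcome was therefore fixed in advance and the test cannot decide. Random shifts reached the observed maximum in 12.2% of draws for gains and in 94.5% for losses. The 4 tumours with broad losses each had 34.2% to 40.5% of bins lower, so they overlap under most shifts. The 94.5% therefore says nothing for or against shared losses. With a threshold of 0.1, 64 bins of chromosome 13 were past the limit for gains, higher in up to 5 tumours, and 3 bins of chromosome 16 for losses, lower in 7. With simple carcinomas 4 and 8 counted once at that threshold, gains reached 4 tumours against a limit of 4 and no longer passed, and losses reached 6 against a limit of 5 in 3 bins. With centring on the mode, 64 bins of chromosome 13 were past the limit of 3, also with the pair counted once.

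The direct comparison of the subtypes asked which chromosomes differ between simple and complex carcinomas. No complex carcinoma had an autosome altered over at least 50% of its length, and the lowest p values lay on chromosomes lost in simple carcinomas. Chromosome 15 differed by -0.18 (SE 0.071), chromosomes 3, 16 and 21 by -0.17 each, and chromosomes 5 and 18 by -0.16 each. Chromosome 13 differed by 0.21 (SE 0.118), and by 0.11 to 0.24 over the alternatives. None passed the threshold in limma, where each of these 7 had an adjusted p of 0.306. In all, limma called 0 of 38 autosomes, with 5 at an unadjusted p under 0.05. It called 0 of 2220 bins, with 339 at an unadjusted p under 0.05 and a lowest adjusted p of 0.322. Leaving out 1 array moved these 339 bins to between 96, without complex carcinoma 4, and 515, without simple carcinoma 6. The 5 autosomes moved to 0 without complex carcinoma 3 or 4 and to 9 without simple carcinoma 6. With arrays weighted by their own spread, limma called 1304 bins, 753 lower and 551 higher. That fit gave complex carcinoma 4 a weight of 26.1 and simple carcinoma 8 a weight of 8.98, against 0.114 to 0.707 for the other simple carcinomas.

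In complex carcinomas no chromosome passed the test against 0. The joint limma fit, whose spread comes largely from the simple carcinomas, called 0 of 2220 bins, with 1 at an unadjusted p under 0.05, and 0 of 38 autosomes. Complex carcinomas fitted alone also gave 0 bins, with 44 at an unadjusted p under 0.05 and a lowest adjusted p of 0.581, and 0 autosomes, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.502. With arrays weighted by their own spread it called 742 bins, 425 lower and 317 higher. Chromosome 13, the most often gained in simple carcinomas, averaged 0.0079 ± 0.011 (SD, n = 4) in complex carcinomas.

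Focal changes, which can single out oncogenes or tumour suppressors, were strongest in simple carcinomas with few whole-chromosome changes past the threshold of 0.2. Simple carcinoma 3 also had smaller whole-chromosome changes, with means of 0.19, 0.15, 0.15 and 0.14 on chromosomes 13, 38, 14 and 34. The description therefore depends on that threshold. Simple carcinoma 3 carried 2 high-level gains, on chromosomes 12 and 16. The gain on chromosome 12 ran from 9100001 to 14200000 with a median log2 ratio of 1.59 and a highest segment of 2.07. The gain on chromosome 16 ran from 9700001 to 14000000 with a median of 1.52 and a highest segment of 2.12. Simple carcinoma 6 carried alternating losses and a gain along chromosome 26. Its median was -0.69 from 3000001 to 6000000, 0.68 from 12400001 to 23200000 and -0.69 from 27500001 to 42000000. The lowest log2 ratio of its segments lay within the last stretch, from 39300001 to 41400000, with a median of -1.93, next to -1.78 from 41400001 to 42000000. The 10 strongest focal segments all lay in these regions of simple carcinomas 3 and 6, and none has a replicate error. Simple carcinoma 4 was lower at a smaller size over a broad part of chromosome 26, which covers the last stretches at -0.33 and -0.28.

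**Figure D4:**
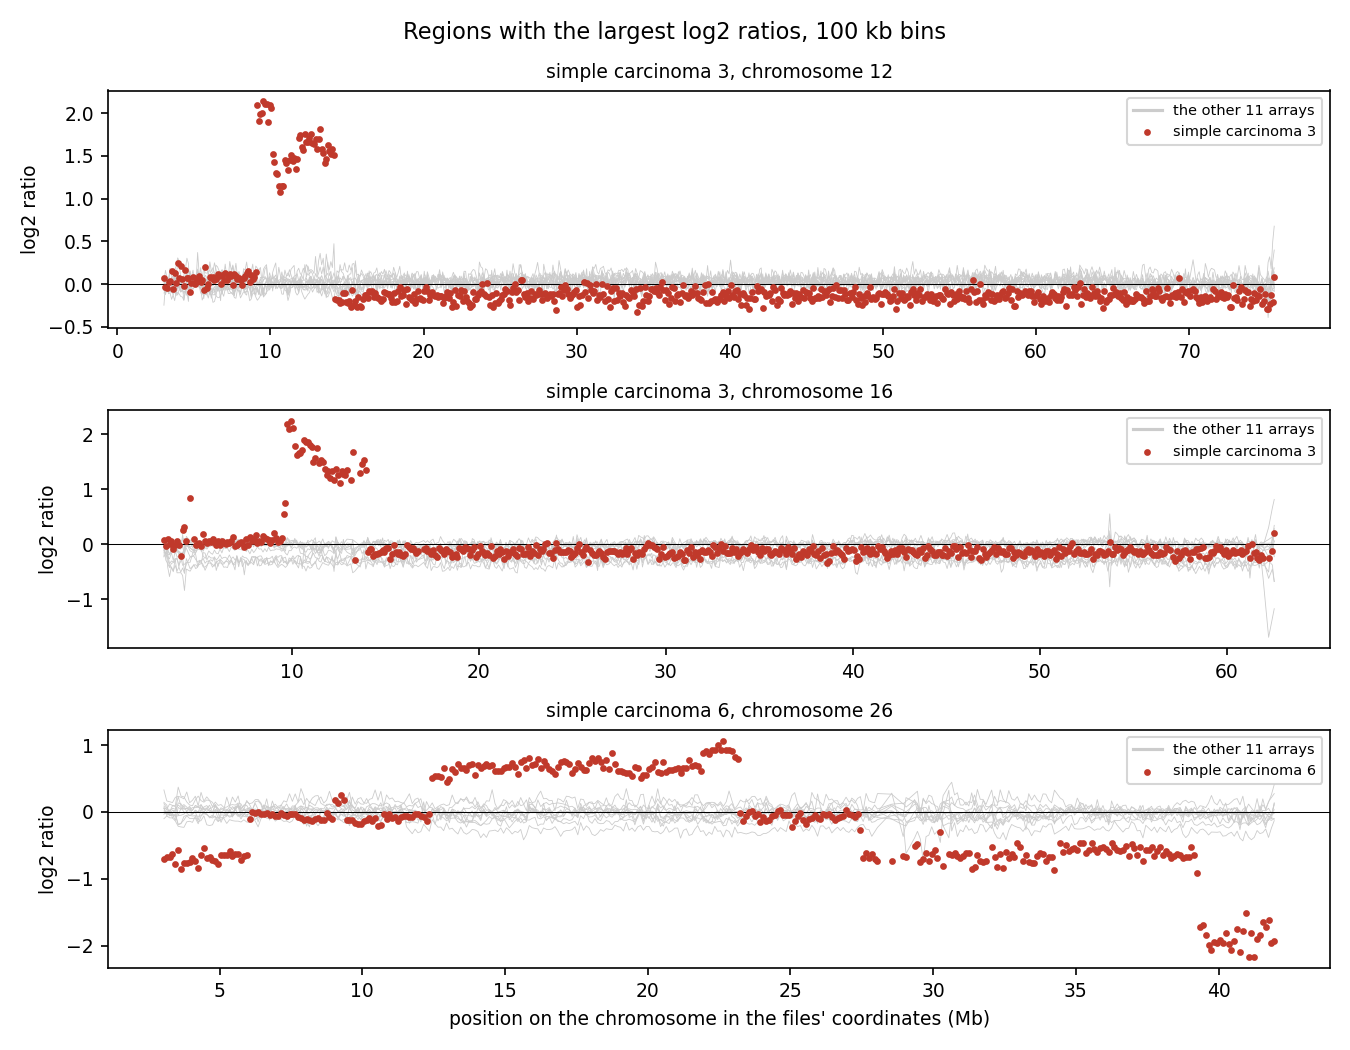
Log2 ratios of 100 kb bins along the chromosomes with the strongest focal changes (horizontal axes, Mb), with the named tumour as points and the other arrays as lines. The gains on chromosomes 12 and 16 in simple carcinoma 3 have medians of 1.59 and 1.52, and the lowest segment on chromosome 26 in simple carcinoma 6 has a median of -1.93.

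Known mammary cancer genes were placed by the chromosome that carries them, since no annotation of the build of the arrays was used. CCND1, the gene of cyclin D1, lies on chromosome 18, which was lower over at least 50% of its length in 4 of 8 simple carcinomas. MYC, a transcription factor that drives growth, lies on chromosome 13, higher in 3. CDKN2A, a gene of cell cycle inhibitors, lies on chromosome 11, lower in 2, with a mean of -0.09 ± 0.14 (SD, n = 8). RB1, which holds back entry into S phase, lies on chromosome 22, lower in 1 simple carcinoma, with a mean of -0.0064 ± 0.13 (SD, n = 8). The receptor gene ERBB2 and the DNA repair gene BRCA1, both on chromosome 9, averaged 0.03 ± 0.075 in simple (SD, n = 8) and -0.03 ± 0.047 in complex carcinomas (SD, n = 4). BRCA2 on chromosome 25, PIK3CA on chromosome 34 and ESR1 on chromosome 1 lie on chromosomes with means of 0.02 ± 0.053, 0.06 ± 0.042 and 0.03 ± 0.048 (SD, n = 8). These are values of whole chromosomes and not of the genes.

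The tumour suppressor list asked whether genes of known loss in breast cancer lie on the 7 chromosomes lost in 4 simple carcinomas. Among the listed genes, chromosome 5 carries CDH1, MAP2K4, ATM, CBFB, NCOR1 and WWOX, and chromosome 16 carries KMT2C, DLC1 and CSMD1. APC lies on chromosome 3 and FBXW7 on chromosome 15. In all, 12 of 29 listed tumour suppressors (41.4%) lie on these chromosomes, against 4128 of 19775 genes in the table (20.9%). Fisher's exact test was not planned, and its 7 chromosomes were chosen from these data. It gave a p of 0.0109, which rose to 0.0983 after adjustment over the 9 lists and did not pass. Genes on the same chromosome are not independent, so this p understates chance.

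None of the other lists passed the test against the background. Of the amplification targets, 7 of 30 lie on the lost chromosomes, CCND1 and EGFR on 18, FGFR1 and ZNF703 on 16, PAK1 and EMSY on 21 and IGF1R on 3, while MYC, PTK2 and KIT lie on the gained chromosome 13. Of the homologous recombination and damage genes, 7 of 22 (31.8%) lie there, namely ATM, CHEK1 and FANCA on chromosome 5, MRE11 on 21, BLM and FANCI on 3 and XRCC2 on 16, with a Fisher's exact p of 0.197. The luminal list had 3 of 15 genes there, PGR on 21, ELF5 on 18 and CDH1 on 5, and the myoepithelial list had 4 of 16. The remaining lists had 3 of 18 PI3K pathway genes, 4 of 24 cell cycle genes, 6 of 27 chromatin genes and 3 of 16 extracellular matrix genes there. Adjusted Fisher's exact p values of these 8 lists lay between 0.886 and 1.0.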

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

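Of the tests in this part, the counts of other splits were chosen only after the result was seen, while the test of brightness against the shared wave was set before. Chance marks about 1 in 20 groups of values as holding an extreme sample, and 48 groups were examined.

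Chromosome 13 in simple carcinoma 1, the chromosome that carries MYC, had a mean log2 ratio of 0.79, far above the other simple carcinomas. Chromosome 22 in simple carcinoma 5, the chromosome that carries RB1, had -0.32, far below the others. Chromosome 31 in simple carcinoma 5 had 0.19, far above the others. Chromosome 3 in complex carcinoma 1 had 0.014 and chromosome 35 in complex carcinoma 1 had -0.020, each apart from the other 3 complex carcinomas by a small amount.

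The spread of 1 Mb log2 ratios differed between the subtypes, by 0.103 with an exact permutation p of 0.0121, or 0.0364 adjusted over 3 measures. Within the hybridisation set that held both subtypes the difference was 0.105 with an exact permutation p of 0.0952, the smallest possible there. The comparison of single bins and autosomes between the subtypes called 0 with limma. All 100 of 100 splits of the arrays into 8 and 4 gave at least the real 0, for bins and for autosomes, with 0 as the highest of the other splits, which a real count of 0 fixes in advance and which therefore says nothing on chance. At an unadjusted p under 0.05 the real split gave 339 bins, 8 of 100 splits gave as many, and the highest other gave 583, so chance cannot be excluded for that count.

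Behind the small values of the complex carcinomas lay a shared long-range wave along the chromosomes, with 83.7% of their variance in a single component. Complex carcinomas 1, 3 and 4 correlated at 0.653 to 0.852 over 1 Mb bins, and complex carcinoma 2 correlated with them at -0.723 to -0.666. Simple carcinomas 2 and 6 shared the wave, at 0.563 to 0.649 and at 0.422 to 0.437 with these 3, and no biological explanation was tested. Probe brightness, as a stand-in for base composition, is a candidate explanation, since the component correlated with it at -0.74 (95% interval -0.793 to -0.667), but base composition itself was not tested.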

How the results depend on the processing

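Of the alternatives in this part, those on simple carcinomas 4 and 8 as a pair, the arrays with channel values, the spatial correction alone, each subtype fitted alone and brightness were tests chosen only after the result was seen. Log2 ratios of chromosomes 3, 5, 13, 15, 16, 18, 21 and 36 were recomputed where an alternative changes the autosome fit. Against 0, 154 values stayed past the threshold, 30 no longer passed, among them 8 for chromosome 13 and 9 for chromosome 36, and 0 reversed. The 176 values between the subtypes had no call to lose and gained none. Against 0, chromosome 5 ranged from -0.23 to -0.10 and chromosome 13 from 0.11 to 0.25. Where no reason is given, the cause was not tested.

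The difference in altered share, 20.4 points, passed the exact permutation test, unadjusted, with a threshold of 0.1 (27.7), 3 times the noise of each array (22.2), centring on the mode (20.7), no segmentation (20.7), without the inflammatory carcinoma (23.3) and with simple carcinomas 4 and 8 as 1 sample (20.5). Adjusted over the 3 measures, it passed only with 3 times the noise, the mode and no segmentation. Leaving out each array gave 17.0 to 23.3. As 1 sample, simple carcinomas 4 and 8 took the mean of their shares of 38.8% and 0%, so that pass rests on the averaging. The unadjusted exact permutation p was 0.0364 without simple carcinoma 8 and 0.115 without simple carcinoma 4. Copy number steps reversed to -7.88 with a threshold of 0.1 and to -12.6 with the spatial correction alone, neither past the test. Leaving out each array moved the difference of 5 steps to between 2.46, without simple carcinoma 5, and 7.58, without complex carcinoma 3. Complex carcinoma 3 alone had 12 steps. The unadjusted difference in spread no longer passed in the set with both subtypes or with the set as a block (0.105 in both), in the 10 arrays with channel values (0.0968) or with the spatial correction alone (0.0860). In that set, 5 against 2 arrays cannot reach a p under 0.05. Adjusted over the 3 measures, the spread passed in 1 of 12 recomputations without an array and in 3 of 12 other alternatives, which were the mode, X included and brightness taken out. Recurrent bins numbered 67 with a threshold of 0.1, 64 with 3 times the noise and 64 with centring on the mode. With simple carcinomas 4 and 8 counted once they numbered 3 with a threshold of 0.1, 64 with 3 times the noise and 64 with centring on the mode.

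For 1 Mb bins, simple against complex, arrayWeights gave 1304 and arrayWeights with brightness taken out 1617. For simple against 0, arrayWeights gave 1518 and arrayWeights with brightness taken out 1802 bins. The set with both subtypes gave 265, the 10 arrays with channel values 449 and the spatial correction alone 337. Simple carcinomas fitted alone gave 0, and leaving out both simple carcinomas 4 and 8 gave 0. Leaving out each array gave 424 to 855. For complex against 0, arrayWeights gave 742 and arrayWeights with brightness taken out 95. The weights came from an iteration that stopped before convergence.

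Autosomes called in simple carcinomas against 0 numbered 7 in the set with both subtypes, 0 with arrayWeights, 0 without both simple carcinomas 4 and 8, 6 in the 10 arrays with channel values, 6 with the spatial correction alone and 5 in simple carcinomas fitted alone. Leaving out each array gave 9 to 19.

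The table of the series held the same values and all arrays the same probes, so these alternatives changed nothing. The segment values of the authors, a correction for base composition and gene-level lists were not run, for want of segments, a genome and an annotation of the build in the sources used here. Changes near -0.15 fell short of the call threshold of -0.2.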

Other observations

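All tests in this part were chosen only after the result was seen, and so were the regions named in it, apart from chromosome 11.

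Several simple carcinomas carried changes of their own beyond those shared with others. Simple carcinoma 7 had mean log2 ratios of 0.30 on chromosome 24 and 0.30 on chromosome 35, whereas simple carcinoma 4 had -0.29 on chromosome 35. Simple carcinoma 5 had a gain on chromosome 6 from 14600001 to 19700000 with a median of 0.61, and simple carcinoma 6 had a loss on chromosome 8 from 37000001 to 38900000 with a median of -0.54. Chromosome 11, which carries CDKN2A, held a short lower stretch from 43400001 to 46200000, at -0.39 in simple carcinoma 4 and -0.18 in simple carcinoma 8, where the means of the chromosome were -0.06 and -0.02. Within it, complex carcinoma 1 had a segment from 44000001 to 44500000 at -0.28.

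At short windows where any array stood apart, the tumour and normal channels of simple carcinoma 4 correlated at 0.206, against 0.602 to 0.901 in the other 9 arrays with channel values, and whether its reference came from the labelled dog was not tested further.

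The X chromosome, left out of the tests, had median log2 ratios of -0.36 in simple carcinoma 7 and -0.24 in simple carcinoma 4. The other simple carcinomas lay from -0.14 to 0.12, and the complex carcinomas from -0.01 to 0.02. The X medians averaged -0.09 ± 0.15 (SD, n = 8) and -0.000125 ± 0.0136 (SD, n = 4), with an exact permutation p of 0.271.

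Simple carcinomas 4 and 8, labelled as different dogs, shared a profile of lost and gained chromosomes at a slope of 0.478. The same changes arising in separate tumours are argued against by their correlation of 0.968 (95% interval 0.953 to 0.976) over 1 Mb bins, since the other 27 pairs of simple carcinomas reached at most 0.671. Simple carcinoma 8 lay on a slide number also used earlier for simple carcinoma 1. Its autosome means had a coefficient of 0.0213 (95% interval 0.00958 to 0.0295) for simple carcinoma 1, beside 0.469 for simple carcinoma 4. That argues against carry-over as the source of the shared profile. The interval lies above 0, so a small carry-over is not excluded. It stays open that tumour DNA of the same dog may be on both arrays. At short windows where simple carcinoma 4 stood apart, the channels of simple carcinoma 8 correlated with it at a mean of 0.415 (95% interval 0.298 to 0.533), and the other 8 arrays with channel values reached at most 0.227.

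Complex carcinoma 3 carried 10 short altered segments, against 3, 0 and 0 in the other complex carcinomas, among them 0.58 on chromosome 15 from 23200001 to 23700000 and 0.47 on chromosome 18 from 32100001 to 32900000. Its reference DNA is labelled as that of the dog of simple carcinoma 1, so inherited differences between dogs may appear as tumour changes. Where complex carcinoma 3 stood apart at short windows, the channels of simple carcinoma 1 correlated with it at a mean of -0.395 (95% interval -0.586 to -0.167), and the lowest of the other 9 arrays was -0.211. The interval includes that value, so this test cannot tell inherited differences from changes of the tumour. Of 143 short windows of complex carcinoma 3, 41 were also windows of simple carcinoma 4. The segments of complex carcinoma 3 on chromosome 14 from 5300001 and chromosome 9 from 20000001 were at 0.244 and -0.289. Simple carcinoma 4 was at 0.435 and 0.282 there. At the segments on chromosomes 15 and 18 named above it was at -0.288 and -0.275, near its chromosome means of -0.270 and -0.286. Whether the shared windows were inherited was not tested.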
